A study of Rattus norvegicus with 12 samples.

How the data were processed

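Total RNA from the bladder body of 12 rats was hybridised, 1 animal per array, to 1-colour Agilent rat arrays with Cy3 labelling, per the labels' protocols. The deposited values were spot intensities, which Agilent Feature Extraction 10.7 had background-subtracted and detrended within each array, per the file headers, with no scaling between arrays. The headers name array design 028279 and genome build rn4. The table of processed values for the whole series equalled the processed signal of the scanner files in 100% of spots at a relative tolerance of 1e-06, so it was on a linear scale without centring, and its array medians lay between 473 and 593. It was not used further, because it would move no value.

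Groups came from the labels: 4 young freely fed, 4 old freely fed and 4 old restricted rats. The 3 comparisons were old against young freely fed rats, restricted against freely fed old rats, and restricted old against young rats. Arrays of young and old freely fed rats lay in different rows of 1 slide, read in 1 scan, and those of restricted rats lay on a second slide read in another scan. Age was therefore compared within a slide, though in different array rows. No slide or scan block could be fitted for the comparisons with restricted rats.

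The log2 processed signal minus the 75th percentile of each array was used. That percentile was 3993 to 4837 for young, 4646 to 4892 for old freely fed and 4123 to 4697 for restricted animals, and the negative control spots had an SD of 25.1 to 30.6, 5.68 to 11.9 and 9.66 to 24.5. The 75th percentile was taken over the 58717 non-control spots, no spot was saturated, and spots marked as outliers in the files were left out unless a probe had no other (91 averages of 1 probe on 1 array). Spots were averaged for each of 30367 probes, and a probe counted as well above background where over 0.5 of its spots did. Names came from the RefSeq accession of the probe, matched without version to a table of the GRCr8 assembly, which was used for names alone. That named 17998 probes (59.3%) with 15154 symbols, and the rest kept the systematic name the files give. Probes well above background on all 4 arrays of at least 1 group were kept (23090), and the probe with the highest mean signal stood for a gene, leaving 20426 features, called genes in the text, of which 12037 had a symbol. Of these features 18564 were well above background on all 12 arrays.

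Tests used R 4.3 and limma 3.58. Linear models were fitted to all 12 arrays, with moderated errors that followed a trend with brightness (eBayes, 9 residual and 2.72 prior degrees of freedom), two-sided, with Benjamini-Hochberg adjustment at 0.05 in each comparison. The 32 gene lists covered immune cells and their signals, cell types of the bladder and of neighbouring glands, muscle, nerve, matrix, antioxidants, metabolism, the clock, stress and senescence. They held 892 symbols, of which 739 were tested, 23 were matched through a synonym and 12 matched no gene. Lists were tested with camera at a preset correlation of 0.01 between genes, and again with an estimated correlation and with fry, and each list was also adjusted over the list alone. Camera compares a list with all other genes, while fry asks whether its genes move one way. The groups, comparisons, tests, lists and alternatives were chosen before the data were examined, except where the text says otherwise.

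Named genes followed a rule. In each comparison it took the 10 largest rises and the 10 largest falls among called genes with a symbol whose groups did not overlap, and up to 4 members of each list with the smallest adjusted p. Some genes that the rule takes are not reported here, though the counts include them. A gene well above background on 0 of 4 arrays of the dimmer group was given a bound. It was the brighter group's mean against the mean, over the dimmer group's arrays, of the higher of the gene's own signal and the lowest signal among probes well above background, and no fold was given where this was under 1. Where 1 to 3 of those arrays were well above background, they kept the gene's own signal and the others were treated in that way, which was added after the results were seen. No bound was given where an array of the brighter group was not above background. The steps were tested on simulated data for the comparison of age over 20426 features, with 50 genes changed at each of 4 sizes. Recovery was 58% at 1.5-fold, 88% at 2-fold, 92% at 3-fold and 98% at 4-fold, with 11 false calls (6.04% of calls), 0 calls in a comparison with no change (limma), and a planted list found at adjusted p = 2.3e-18 with 0 of 31 other lists (camera). The simulated genes varied independently of each other, so this list result cannot show how camera treats lists of correlated genes.

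Alternatives were quantile scaling, median centring, normexp background correction (offset 50) with either scaling, other filters on dim probes, all probes or another probe of a gene, a fit without the brightness trend, array weights, fits of 2 groups only, stricter thresholds, the replicate number as a block, and leaving out each animal in turn. Normexp used the median spot and background signals, because the files analysed here held no mean signal. Leaving out old freely fed replicates 2 and 4 together was added after the data were seen. Chance overlap of comparisons that share arrays was simulated with 100 draws, and random lists were drawn 10000 times from genes of matched brightness.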

Results

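Gene expression was measured in the bladder body of 12 male Fischer 344 rats, with 1 animal on each 1-colour array. The animals formed 3 groups of 4: young rats of 6 months with free access to food, old rats of 25 to 28 months with free access to food, and old rats of the same ages that had eaten on 3 days a week from the age of 6 weeks, an intake about 40% lower by the labels. The title of the series asks which inflammatory and oxidative changes come with age in the bladder and whether restriction prevents them. Probes well above background numbered 21660 to 22294 of 30367 on the arrays of young rats, 23373 to 24644 on those of old freely fed rats and 22567 to 23200 on those of old restricted rats. Arrays of the same group correlated at r = 0.985 to 0.997 across genes, and arrays of different groups at 0.981 to 0.994. Old freely fed replicate 2 lay apart on the first principal component, at 51.9 against 7.28 to 13.7 for the other 3 animals of its group. Negative control spots, scaled like the genes, had mean log2 signals of -9.08 on the arrays of young, -10.2 on those of old freely fed and -9.69 on those of old restricted rats. Levels are log2 signals relative to the 75th percentile of each array, given as mean ± SD with n = 4 animals. The median of a gene list is that of its members' log2 changes. A list is said to lose its call or to move without an animal where leaving that animal out ended its call or moved its median by over 1.5 times, with the median then left in brackets. The same words are used for quantile scaling, for normexp background correction alone or followed by quantile scaling, and for fits with no filter on dim probes. Tests were two-sided, and the number of arrays limits the precision. Their p-values and errors measure the spread between animals pooled over all 3 groups, also where a comparison uses 2 of them. Of the 54 list calls made by camera across the comparisons, 0 held with an estimated correlation (smallest adjusted p 0.168, 0.182 and 0.461 by comparison, with 4, 4 and 0 of 32 lists at an unadjusted p under 0.05) and 16 held with fry. With age these were the T and NK, cytokine, B cell, smooth muscle, respiration and prostate lists. With restriction they were the T and NK, cytokine, lipid synthesis, clock and adipocyte lists. Between restricted old and young rats they were the lipid synthesis, smooth muscle, striated muscle, nerve and prostate lists.

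The first comparison was that of age, old against young rats with free access to food. In old rats the markers of T and NK cells were higher: of 26 tested, 12 rose and 0 fell, and 23 were higher when adjusted over the list alone (median 1.09, camera adjusted p = 1.3e-21, adjusted p = 0.17 with an estimated correlation). Cd7 rose 2.03-fold (log2 1.02, SE 0.10, adjusted p = 0.0028), from -2.64 ± 0.14 to -1.62 ± 0.21. Cd2, a T cell adhesion receptor, rose 2.31-fold, and Cd3d, a chain of the T cell receptor complex, rose 1.84-fold. Cd6 rose 2.44-fold by its brightest probe, while another Cd6 probe gave a log2 change of -0.18 (adjusted p = 0.22). Outside the list, Gzmc, a granzyme of cytotoxic lymphocytes, rose 13.8-fold (log2 3.79, SE 0.76, adjusted p = 0.029), and did not pass without young replicates 1, 2 or 3 or old freely fed replicate 3. Its rise was 7.26-fold without old freely fed replicate 2, which lay at 1.53 against -2.46 to -1.67 in the other 3. The surface protein gene Art2b was well above background in 4 of 4 old animals and in 0 of 4 young, which makes it at least 1.6-fold higher.

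Other immune groups moved the same way with fewer genes past the threshold. Only the cytokine and the B and plasma cell lists among them also passed with fry (adjusted p = 0.033 and 0.042). Of 28 cytokine and chemokine genes, 2 rose and 17 were higher when adjusted over the list alone (median 0.45, camera adjusted p = 3.0e-10, adjusted p = 0.27 with an estimated correlation). The 2 genes were Il1a, which encodes the cytokine interleukin 1 alpha, up at least 5.41-fold and well above background in only 1 of 4 young animals, and the chemokine gene Ccl7, up 2.35-fold. Il1a did not pass in 9 of the 12 fits that left out 1 animal, and its bound was 3.1-fold without old freely fed replicate 3, at -2.10 against -6.29 to -4.22 in the others, and 8.14-fold without replicate 4. Among 25 macrophage and dendritic cell markers 3 rose (12 higher and 1 lower adjusted over the list alone; median 0.53, camera adjusted p = 3.9e-10, adjusted p = 0.28 with an estimated correlation). Gpnmb rose 1.55-fold, Laptm5 1.65-fold and Ptprc 1.89-fold. Among 18 B and plasma cell markers 3 rose (9 adjusted over the list alone; median 0.29, camera adjusted p = 3.0e-05, adjusted p = 0.27 with an estimated correlation). They included Spib, at least 2.83-fold higher, and Cd72, at least 1.8-fold, neither of them well above background in a young animal. In the MHC class II list 1 of 12 genes rose, RT1-Bb by 1.48-fold, and 7 were higher adjusted over the list alone (median 0.30, camera adjusted p = 2.2e-06, adjusted p = 0.28 with an estimated correlation). In the complement list 1 of 19 rose, Itgb2 by 2.01-fold, with 4 higher adjusted over the list alone (median 0.50, camera adjusted p = 1.6e-08, adjusted p = 0.29 with an estimated correlation). C3, the central complement component, had a log2 change of 1.96 (adjusted p = 0.07), or 1.28 without old freely fed replicate 2, and did not pass. In the acute phase list 2 of 22 rose, Ptx3 by 2.37-fold and the endotoxin receptor gene Tlr4 by 1.38-fold (3 adjusted over the list alone; median 0.33, camera adjusted p = 3.3e-05, adjusted p = 0.28 with an estimated correlation). The 26 interferon response genes had a median log2 change of 0.75 (camera adjusted p = 2.2e-08, adjusted p = 0.39 with an estimated correlation) and 0 genes past the threshold (6 higher and 0 lower at an unadjusted p under 0.05, limma). The macrophage and dendritic cell list moved without old freely fed replicate 2 (0.31). The MHC class II list moved without old freely fed replicate 4 (0.50). The complement list moved without old freely fed replicate 2 (0.23). The acute phase list moved without old freely fed replicate 2 (0.17). The interferon list moved without old freely fed replicate 2 (0.27). The B and plasma cell list moved with normexp (0.11).

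Contractile and mitochondrial genes were lower in old than in young rats with the main scaling, and less so with quantile scaling. Of 27 smooth muscle genes 6 fell and 0 rose, and 19 were lower adjusted over the list alone (median -0.30, camera adjusted p = 1.3e-08, adjusted p = 0.28 with an estimated correlation). They included Kcnma1, the pore of the large-conductance calcium-activated potassium channel, lower by 1.29-fold, the light chain gene Myl9 by 1.33-fold, the smooth muscle myosin heavy chain gene Myh11 by 1.19-fold and Synm by 1.23-fold. Of 40 genes of mitochondrial respiration 6 fell and 18 were lower adjusted over the list alone (median -0.14, camera adjusted p = 9.5e-08, adjusted p = 0.28 with an estimated correlation). Among them were Cox6c, lower by 1.2-fold, Cox6a2 by 1.98-fold, Atp5f1b by 1.17-fold and Ppargc1a, a coactivator of mitochondrial biogenesis, by 1.6-fold. In the collagen and matrix list 2 of 28 fell, Col1a2 by 1.2-fold and Loxl2 by 1.73-fold (7 lower and 1 higher adjusted over the list alone; median -0.21, camera adjusted p = 0.0015, adjusted p = 0.44 with an estimated correlation). In the lipid synthesis list 2 of 22 fell (5 adjusted over the list alone; median -0.19, camera adjusted p = 0.0012, adjusted p = 0.44 with an estimated correlation). Srebf2, a regulator of sterol synthesis, fell by 1.24-fold. Of 40 antioxidant and oxidative stress genes 4 rose and 0 fell (4 higher and 3 lower adjusted over the list alone), and the list as a whole did not pass (median log2 change 0.02, camera adjusted p = 0.11). They were the uncoupling protein genes Ucp2 (1.33-fold) and Ucp3 (1.63-fold), Nfe2l2 (1.18-fold), which encodes the antioxidant regulator Nrf2, and Gpx2 (1.47-fold). In the list of bladder receptors and channels, which did not pass, 3 of 39 rose, namely P2rx4, Trpv2 and Gja1, and 3 fell, namely Trpm4 (both Gja1 and Trpm4 being named only after their values were seen), the muscarinic receptor gene Chrm3 by 1.43-fold and the purinergic receptor gene P2ry1 by 1.42-fold. The smooth muscle list moved with quantile scaling (-0.20), and the respiration list with quantile scaling (-0.07) and with normexp and quantile scaling (-0.06). The collagen and matrix list (-0.08) and the lipid synthesis list (-0.15) lost their calls without old freely fed replicates 2 and 4 together.

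Prostate and seminal vesicle markers, from glands that lie next to the bladder, also differed. Of 8 tested 2 fell (3 adjusted over the list alone; median -0.56, camera adjusted p = 0.0077, adjusted p = 0.29 with an estimated correlation). Andpro was well above background in 4 of 4 young animals and 1 of 4 old ones, which makes it at least 17.4-fold lower (limma adjusted p = 0.02). Its level was -5.78 in old freely fed replicate 3 and -10.3 to -9.85 in the other 3, and it did not pass without young replicate 2. The bound was 11.5-fold without that animal and 26.2-fold without old freely fed replicate 3. The prostate list moved without young replicate 2 (-0.35), old freely fed replicate 2 (-0.37) and 3 (-0.87), with normexp (-0.36) and with normexp and quantile scaling (-0.29), and lost its call without old freely fed replicates 2 and 4 together (-0.29). The tissue kallikrein gene Klk1 fell by 2.36-fold, and outside the list its relatives Klk1c8 and Klk1c2 fell by 3.07-fold and 2.64-fold. In the list of nerve genes, which did not pass as a whole, Stmn2 fell by 2.03-fold and Prph by 1.33-fold. Fibroblast markers Pdgfrl and Cd34 fell by 1.52-fold and 1.5-fold, and the striated muscle gene Tnnc2 by 2.27-fold, in lists that did not pass. The basal keratin gene Krt5 rose 1.58-fold, while the 27 urothelial genes as a list did not pass (median log2 change 0.02 and -0.03 with normexp, camera adjusted p = 0.18). Slpi, Pf4 and Akr1b8 rose 2.45, 1.54 and 1.31-fold in the mesothelial, platelet and detoxification lists. None of these 3 lists passed, nor did the cell cycle, clock, endothelial, heat shock and senescence lists.

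Among single genes, the changes of greatest size that separated all 4 old from all 4 young animals included Krt6c, a keratin of stressed epithelia, up 13.6-fold (log2 3.77, SE 0.49, adjusted p = 0.0069). The collagenase gene Mmp13 rose 9.82-fold (6.55-fold without old freely fed replicate 3) and the stromelysin gene Mmp3 3.39-fold, in a matrix turnover list in which 2 of 27 rose (median 0.08, camera adjusted p = 0.0092, adjusted p = 0.28 with an estimated correlation). Slc51a rose at least 2.49-fold and was well above background in 1 of 4 young animals. Akr1c3 rose at least 4.78-fold and was above background in 2 of 4. Ly6d was at least 1.81-fold higher and the tight junction gene Cldn3 at least 1.65-fold, neither being above background in young rats. Krt24 was at least 4.51-fold lower in old rats, where it was above background in 0 of 4. Cyp2f4 fell by 3.14-fold, the carboxylesterase gene Ces1dl1 by 2.27-fold, Igsf1 by 2.26-fold and the interleukin 13 decoy receptor gene Il13ra2 by 2.25-fold. Angptl4 and Lpl, which encode an inhibitor of lipoprotein lipase and the lipase itself, rose 2.67-fold and 1.42-fold in the adipocyte list (2 of 21 rose; median 0.18, camera adjusted p = 0.0053, adjusted p = 0.28 with an estimated correlation). In the fasting list 2 of 32 rose and 1 fell, the latter being the growth factor gene Igf1 by 1.38-fold (median 0.10, camera adjusted p = 3.3e-04, adjusted p = 0.28 with an estimated correlation). Immediate early genes (median 0.22, camera adjusted p = 0.0011, adjusted p = 0.44 with an estimated correlation) and mast cell and granulocyte markers (median 0.26, camera adjusted p = 0.0069, adjusted p = 0.53 with an estimated correlation) passed as lists with 0 single genes (5 higher and 0 lower at an unadjusted p under 0.05, and 3 higher and 0 lower at an unadjusted p under 0.05, limma). The matrix turnover list lost its call without young replicate 4 (0.04) and old freely fed replicate 1 (0.04) and moved without young replicate 3 (0.05), old freely fed replicate 3 (0.13) and 4 (0.14). The adipocyte list moved without old freely fed replicate 4 (0.10), with normexp (0.08) and with normexp and quantile scaling (0.11). The fasting list moved without young replicate 1 (0.06) and with normexp (0.05). The immediate early list lost its call without old freely fed replicate 3 (-0.04, a change of sign) and moved without young replicate 3 (0.13), old freely fed replicate 2 (0.34) and 4 (0.34). The mast cell and granulocyte list lost its call without old freely fed replicate 1 (0.14) and 2 (0.06) and moved without young replicate 3 (0.18), old freely fed replicate 3 (0.48) and 4 (0.47) and with normexp (0.17).

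In all, 332 genes were higher and 428 lower in old than in young rats among 20426 tested (limma, adjusted p under 0.05). Of these 112 and 17 changed at least 2-fold. Over all genes tested, called or not, the animals of both groups did not overlap for 3076 (15.1%), where chance gives 2.86%. Quantile scaling gave 364 higher and 152 lower, median centring 356 and 306, and quantile scaling after normexp 287 and 124. Calls followed brightness, with 108 higher and 19 lower among the dimmest 5107 genes and 30 and 177 among the brightest 5107. An intensity-dependent offset between the array rows was not tested for age, so it may have contributed to these calls. Counts moved by over 1.5 times without young replicates 1 (94 higher, 86 lower), 2 (73, 48) and 3 (115, 125), old freely fed replicates 2 (192, 90), 3 (156, 87) and 4 (265 lower), and old restricted replicates 1 (210, 218), 2 (160, 129) and 4 (254 lower). Of the 67 genes past the threshold that were named by rule, only Krt6c, Ly6d, Cldn3, Krt24, Cd7, Cd6, Cd2, Cd3d, Mmp3, P2ry1, Cox6c and Akr1b8 passed in each of the 12 fits that left out 1 animal. Cd72 did not pass in any of these 12 fits, and Gpx2 and Gja1 did not pass in 11. Named genes that no longer passed were, with normexp, Ly6d, Art2b, Il1a, Cd72, Itgb2, Tlr4, Trpv2, Myh11, Loxl2 and Igf1. With quantile scaling these were Il1a, Cyp2f4, Myl9, Myh11, Synm, Cox6c, Atp5f1b, Col1a2, Stmn2, Tnnc2, Igf1, Cd34 and Trpm4. By another probe they were Igsf1, Cd6, RT1-Bb, Ptprc, Ptx3, Gpx2, Kcnma1, Synm, Stmn2 and Igf1, and another probe of Krt6c gave a log2 change of 1.76. Without the brightness trend they were Akr1c3, Il1a, Cyp2f4, Cd72, Ccl7, Itgb2, Ptprc, Tlr4, Lpl, Nfe2l2, Gpx2, Myh11, Synm, Atp5f1b, Col1a2, Loxl2, Krt5, Stmn2, Tnnc2, Igf1, Cd34, Pf4 and Gja1. A fit of the 8 arrays of these groups alone, which share a slide and a scan, gave 67 higher and 27 lower. The main fit also takes its spread from the restricted arrays. Mean correlations of an array with its own group were 0.995 to 0.996 there, 0.989 to 0.992 in old freely fed and 0.992 to 0.994 in young rats. The closer restricted arrays may thus have lowered the error used for age.

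**Figure D1:**
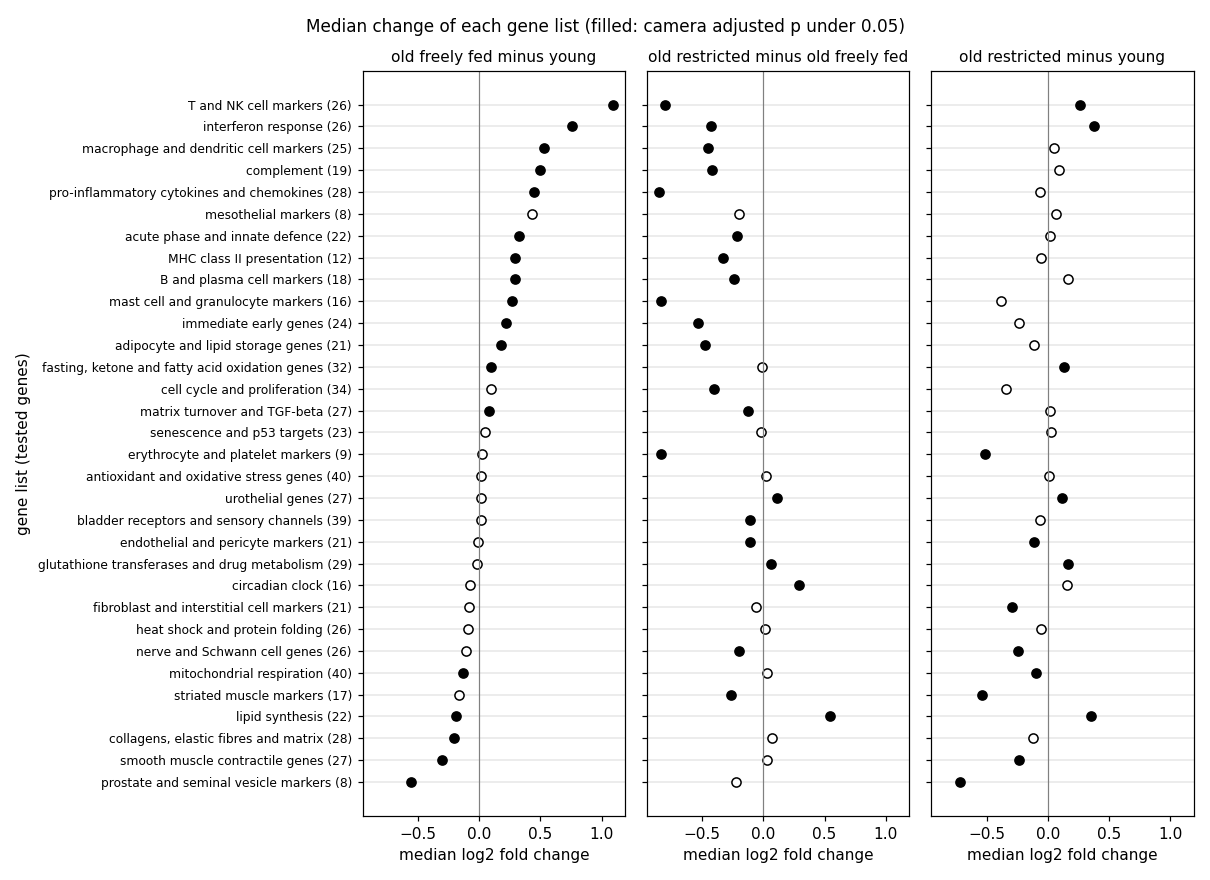
Median log2 fold change (x axis) of the tested genes of each of 32 gene lists (y axis, number of tested genes in brackets) in the 3 comparisons, with filled points for lists past an adjusted p of 0.05 in the camera test. The T and NK cell list lies at 1.09 for old against young freely fed rats and at -0.80 for restricted against freely fed old rats.

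The second comparison was that of restricted with freely fed old rats. Genes of sterol and fatty acid synthesis were higher in restricted rats: of 22 tested, 14 rose and 0 fell, with 16 higher adjusted over the list alone (median 0.55, camera adjusted p = 1.3e-15, adjusted p = 0.18 with an estimated correlation). Fdps, an enzyme of the mevalonate pathway, rose 1.67-fold (log2 0.74, SE 0.10, adjusted p = 0.0035), from 1.25 ± 0.18 to 1.98 ± 0.09. The desaturase gene Scd2 rose 1.66-fold and Srebf2 1.28-fold. Outside the list, the fatty acid ligase gene Acsbg1 rose 2.53-fold (log2 1.34, SE 0.14, adjusted p = 0.0019).

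Clock genes moved in both directions. Of 16 tested 6 rose and 3 fell (8 and 3 adjusted over the list alone; median 0.29, camera adjusted p = 0.02, adjusted p = 0.3 with an estimated correlation). The clock output genes Dbp and Tef rose 3.85-fold and 2.51-fold, the repressor gene Per2 3.72-fold and Ciart 5.44-fold. Bmal1, the activator of the clock's core loop, fell by 3.31-fold (log2 -1.73, SE 0.25, adjusted p = 0.0051) and Npas2 by 1.78-fold. The glucocorticoid-responsive genes Tsc22d3 and Fkbp5 rose 1.5-fold and 2.36-fold. The clock list lost its call without old freely fed replicate 4 (0.25) and old restricted replicate 4 (0.21).

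**Figure D2:**
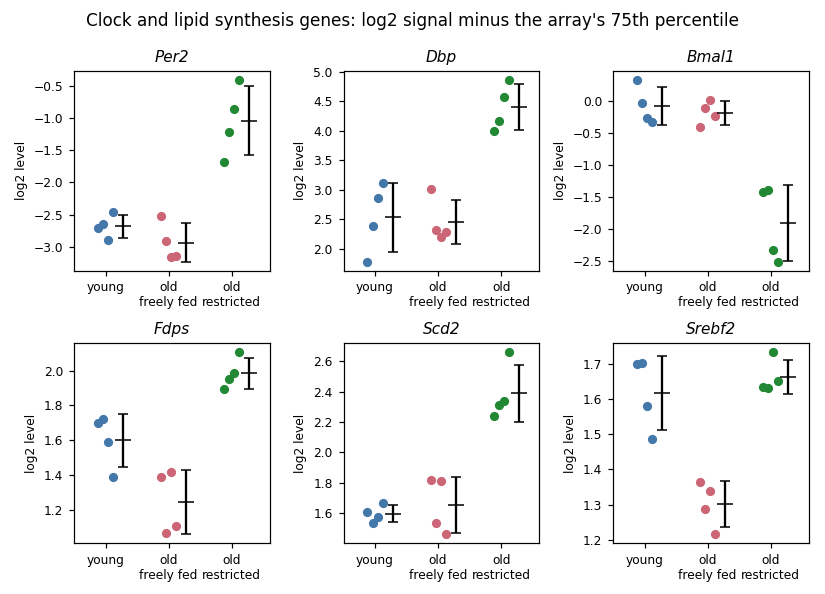
Log2 signal relative to the 75th percentile of the array (y axis) of 3 clock genes and 3 lipid synthesis genes in each of 4 animals per group (x axis), with the mean and SD beside the points. Bmal1 had a mean of -0.19 in old freely fed and -1.92 in old restricted rats, while Dbp went from 2.46 to 4.40.

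Immune genes were lower in restricted than in freely fed old rats. Among the immune lists only those of cytokines and of T and NK cells also passed with fry (adjusted p = 0.016 and 0.014). Of 28 cytokine and chemokine genes 6 fell and 0 rose, with 15 lower adjusted over the list alone (median -0.86, camera adjusted p = 2.8e-12, adjusted p = 0.18 with an estimated correlation). The neutrophil-attracting chemokine genes Cxcl2 and Cxcl1 fell by 5.4-fold and 2.47-fold, the monocyte-attracting Ccl2 by 3.18-fold and Ccl3 by 2.59-fold (log2 -1.37, SE 0.18, adjusted p = 0.0041). Of 26 T and NK cell markers 5 fell, and 22 were lower adjusted over the list alone (median -0.80, camera adjusted p = 4.5e-15, adjusted p = 0.18 with an estimated correlation). Cd7 fell by 2.01-fold and Cd3d by 1.64-fold. Cd6 fell by 1.71-fold by its brightest probe, and another probe gave a log2 change of 0.03. In the MHC class II list 3 of 12 fell (6 adjusted over the list alone; median -0.33, camera adjusted p = 1.9e-05, adjusted p = 0.3 with an estimated correlation). RT1-Bb, RT1-Da and RT1-Db1 fell by 1.62, 1.62 and 1.56-fold. Of 25 macrophage and dendritic cell markers 2 fell (9 adjusted over the list alone; median -0.45, camera adjusted p = 4.3e-08, adjusted p = 0.3 with an estimated correlation). Cd53 fell by 1.75-fold and Spp1 by at least 1.77-fold, being above background in 0 of 4 restricted animals. In the mast cell and granulocyte list 1 of 16 fell, Cxcr2 by at least 2.19-fold with 3 of 4 restricted animals above background (median -0.83, camera adjusted p = 1.6e-06, adjusted p = 0.3 with an estimated correlation). Complement, acute phase, B cell and interferon lists passed downwards with 0 genes past the threshold, at median log2 changes of -0.42, -0.22, -0.24 and -0.43 (adjusted p = 0.3, 0.3, 0.3 and 0.58 with an estimated correlation). Unadjusted p under 0.05 (limma) was met by 8, 8, 6 and 3 lower members. Immediate early and cell cycle genes likewise had medians of -0.54 and -0.40 with 0 genes past the threshold (camera adjusted p = 2.0e-07 and 3.9e-05, adjusted p = 0.3 and 0.5 with an estimated correlation; 10 and 4 lower at an unadjusted p under 0.05). The cytokine and chemokine list moved without old freely fed replicate 2 (-0.36). The MHC class II list moved without old freely fed replicate 4 (-0.55). The mast cell and granulocyte list moved without old freely fed replicate 1 (-0.56) and 2 (-0.48). The complement list moved without old freely fed replicate 2 (-0.14). The acute phase list moved without old freely fed replicate 2 (-0.13). The B and plasma cell list lost its call without old freely fed replicate 2 (-0.22), old restricted replicate 2 (-0.24) and 4 (-0.17) and moved with normexp (-0.05) and with normexp and quantile scaling (-0.16). The interferon list lost its call without old freely fed replicate 2 (0.16, a change of sign) and moved without old freely fed replicate 3 (-0.64) and old restricted replicate 3 (-0.69). The immediate early list moved without old freely fed replicate 3 (-0.31). The cell cycle list moved without old freely fed replicate 1 (-0.19).

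**Figure D3:**
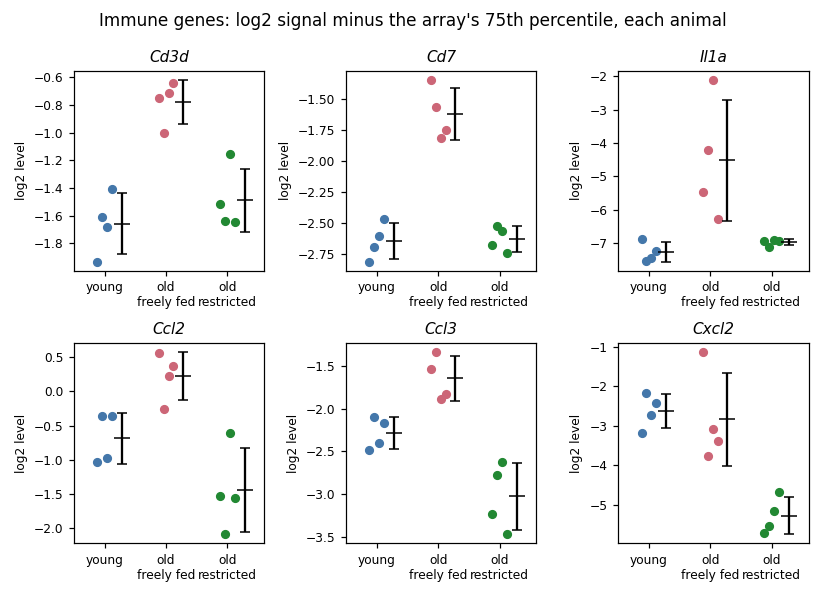
Log2 signal relative to the 75th percentile of the array (y axis) of 6 immune genes in each of 4 animals per group (x axis), with the mean and SD beside the points. Mean levels of Ccl2 were -0.68 in young, 0.23 in old freely fed and -1.44 in old restricted rats.

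Genes of lipid uptake and storage were lower in restricted rats. Of 21 adipocyte and lipid storage genes 3 fell and 1 rose (8 lower adjusted over the list alone; median -0.48, camera adjusted p = 7.8e-05, adjusted p = 0.19 with an estimated correlation). Lpl fell by 2.31-fold (log2 -1.21, SE 0.12, adjusted p = 0.0019), Angptl4 by 3.91-fold and G0s2, an inhibitor of triglyceride breakdown, by 1.75-fold, while the lipid synthesis gene Agpat2 rose 1.19-fold. In the fasting list, which did not pass, 3 of 32 rose, including the ketone body enzyme gene Bdh1 by 1.28-fold, and 2 fell. The latter included Pck1, the gluconeogenic enzyme gene, lower by at least 4.99-fold and above background in 2 of 4 restricted animals. Pck1 did not pass in 11 of the 12 fits that left out 1 animal. In the matrix list, also not past, Tnc, Thbs2 and Col8a1 rose 1.48, 1.33 and 1.45-fold. In the matrix turnover list Mmp14 fell by 1.28-fold (median -0.13, camera adjusted p = 0.012, adjusted p = 0.3 with an estimated correlation). Endothelial and pericyte markers Plvap, Rgs5 and Pecam1 fell by 1.31, 1.5 and 1.29-fold (3 of 21; median -0.11, camera adjusted p = 0.0017, adjusted p = 0.3 with an estimated correlation). The platelet gene Pf4 fell by 1.8-fold (1 of 9 erythrocyte and platelet markers; median -0.84, camera adjusted p = 0.0017, adjusted p = 0.3 with an estimated correlation). Striated muscle genes Atp2a1 and Actc1 fell by 2.26-fold and 2.4-fold (2 of 17; median -0.26, camera adjusted p = 0.0017, adjusted p = 0.3 with an estimated correlation). The single members that fell in the respiration, smooth muscle and mesothelial lists, which did not pass, were Cox6a2 (2.27-fold), the calcium store protein gene Casq2 (1.56-fold) and Slpi (2.58-fold). Detoxifying enzyme genes Ephx1, Gsta3 and Adh7 rose 1.37, 1.2 and 1.36-fold and Gsta2 fell by 2.84-fold (median 0.06, camera adjusted p = 0.049, adjusted p = 0.54 with an estimated correlation). Of 40 antioxidant genes 0 passed in either direction (limma; 3 higher and 2 lower at an unadjusted p under 0.05). Among bladder receptors and channels Trpm4 and P2ry1 rose 1.35 and 1.29-fold and the adrenergic receptor gene Adra1d fell by 1.72-fold (median -0.11, camera adjusted p = 0.045, adjusted p = 0.3 with an estimated correlation). Herpud1, a gene of endoplasmic reticulum protein breakdown, rose 1.34-fold in a heat shock and folding list that did not pass. Nerve genes (median -0.20, camera adjusted p = 0.0043, adjusted p = 0.3 with an estimated correlation) and urothelial genes (median 0.11, camera adjusted p = 0.027, adjusted p = 0.36 with an estimated correlation) passed as lists with 0 single genes (limma; 1 higher and 6 lower at an unadjusted p under 0.05, and 9 higher and 1 lower at an unadjusted p under 0.05). Apod fell and Cxcl14 rose in the fibroblast list, which did not pass, nor did the prostate and senescence lists. The adipocyte list moved without old freely fed replicate 2 (-0.32), old restricted replicate 2 (-0.30) and 3 (-0.28). The matrix turnover list moved without old freely fed replicate 1 (-0.08) and 4 (-0.19). The erythrocyte and platelet list moved without old freely fed replicate 2 (-0.32). The striated muscle list moved without old freely fed replicate 1 (-0.15), 2 (-0.40) and 4 (-0.47). The detoxification list lost its call without young replicate 2 (0.06), 3 (0.06), 4 (0.06), old freely fed replicate 1 (0.08), 2 (0.03), old restricted replicate 3 (0.10) and 4 (0.07) and moved without old freely fed replicate 4 (0.16) and old restricted replicate 1 (0.10). It also lost its call with quantile scaling (0.07), normexp (0.11) and no filter on dim probes (0.06), and moved with normexp and quantile scaling (0.04). The receptor and channel list lost its call without young replicate 1 (-0.11), old freely fed replicate 3 (-0.11), 4 (-0.06), old restricted replicate 1 (-0.12) and 2 (-0.09) and moved without old restricted replicate 3 (-0.04). It also lost its call with quantile scaling (-0.06) and normexp (-0.02), and moved with both (-0.05). The urothelial list lost its call without young replicate 1 (0.11), old freely fed replicate 4 (0.08) and old restricted replicate 3 (0.07) and moved without old restricted replicate 4 (0.07). It also lost its call with quantile scaling (0.08) and normexp (0.10). The nerve list moved with normexp (-0.13).

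Further genes with large changes that separated the 2 old groups were Sertm1, Atp2b3 and Aard, up 2.85, 2.52 and 2.39-fold, and Alkal2 and Galntl5, down by 3.51-fold and at least 3.57-fold, the last with 3 of 4 restricted animals above background. Rnase2, a ribonuclease gene of eosinophils, was at least 5.91-fold lower (3.51-fold without old freely fed replicate 2), Gsc at least 1.78-fold, Vom1r21 at least 1.53-fold and Sirpb3 at least 1.49-fold, each above background in 0 of 4 restricted animals. Krt24 was higher, with 3 of 4 restricted and 0 of 4 freely fed animals above background (limma adjusted p = 0.0041).

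In all, 331 genes were higher and 413 lower in restricted than in freely fed old rats (limma). Of these, 26 and 115 changed at least 2-fold. The animals did not overlap for 3001 (14.7%) of all genes tested, against a chance share of 2.86%. The normexp background correction gave 580 higher and 325 lower. Calls differed with brightness here too, with 69 higher and 197 lower among the dimmest 5107 genes and 69 and 43 among the brightest 5107. An intensity-dependent offset between the slides was not tested for these counts. Counts fell by over 1.5 times without old freely fed replicates 1 (186 higher, 204 lower), 2 (187, 260) and 3 (172, 248) and old restricted replicates 1 (208 higher), 2 (117, 151), 3 (187, 267) and 4 (135, 172). Of the 66 genes named by rule, 33 passed in each of the 12 fits that left out 1 animal. Pck1 and Actc1 did not pass in 11 of these fits, and Gsta2, Adh7 and Pecam1 in 10. Rnase2, Spp1, Vom1r21, Sirpb3 and Gsc no longer passed with normexp, Adh7, Gsta2, Actc1 and Cxcl14 with quantile scaling, and Cd6, Npas2 and Gsta3 by another probe. Pck1, Cd53, Pecam1, Gsta3, Adh7, Gsta2, Actc1, Apod and Cxcl14 did not pass without the brightness trend. Restricted arrays lay on a slide and in a scan of their own, and in another array row than the freely fed old arrays. Slide, scan, row and restriction therefore cannot be told apart here.

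The third comparison set restricted old rats against young rats. Genes that rose included those of lipid synthesis, 8 of 22 (11 adjusted over the list alone; median 0.35, camera adjusted p = 3.3e-07, adjusted p = 0.46 with an estimated correlation). Scd2 rose 1.73-fold, Dhcr7 1.43-fold and Mvd 1.33-fold. Clock genes again split, with 8 of 16 higher and 3 lower in a list that did not pass. Dbp and Per2 rose 3.65 and 3.12-fold, Ciart at least 5.79-fold with 3 of 4 young animals above background, and Bmal1 and Npas2 fell by 3.58 and 1.88-fold. Detoxifying enzyme genes had 8 of 29 higher and 2 lower (median 0.17, camera adjusted p = 0.0043, adjusted p = 0.46 with an estimated correlation). Adh7, Akr1b8 and Gsta1 rose 1.81, 1.36 and 1.25-fold and Ces1d fell by 2.45-fold. Of 40 antioxidant genes 5 rose, including the quinone reductase gene Nqo1 by 1.46-fold, Prdx6 by 1.18-fold and Nfe2l2 by 1.16-fold, and 1 fell, the extracellular superoxide dismutase gene Sod3 by 1.23-fold, in a list that did not pass. In the fasting list 7 of 32 rose and 2 fell (median 0.13, camera adjusted p = 0.019, adjusted p = 0.46 with an estimated correlation). Klf15 and Bdh1 rose 2.13 and 1.37-fold and Igf1 fell by 1.57-fold. Urothelial genes had 3 of 27 higher and 1 lower (median 0.12, camera adjusted p = 0.0043, adjusted p = 0.46 with an estimated correlation). Krt5 rose 2.01-fold and Klf5 1.26-fold. The fasting list lost its call without old restricted replicate 1 (0.11) and moved without young replicate 1 (0.08).

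Muscle and nerve genes were lower in restricted old than in young rats. Of 27 smooth muscle genes 9 fell and 0 rose (19 lower adjusted over the list alone; median -0.24, camera adjusted p = 3.3e-07, adjusted p = 0.46 with an estimated correlation). Casq2 fell by 2.25-fold (log2 -1.17, SE 0.13, adjusted p = 0.0012) and Kcnma1 by 1.29-fold. Among 17 striated muscle markers 6 fell (median -0.54, camera adjusted p = 8.2e-04, adjusted p = 0.46 with an estimated correlation). Tnnc2, Tnnt3 and Actc1 fell by 2.59, 1.88 and 2.65-fold. Of 26 nerve and Schwann cell genes 5 fell (8 lower and 1 higher adjusted over the list alone; median -0.25, camera adjusted p = 0.003, adjusted p = 0.46 with an estimated correlation). They included the neurofilament genes Nefl and Nefm, lower by 2.65 and 2.45-fold, the receptor gene Gfra3 of sensory neurons by 2.02-fold and Stmn2 by 2.18-fold. Muscarinic receptor genes Chrm2 and Chrm3 fell by 1.61 and 1.46-fold and Adra1d by 2.01-fold, while Asic1 was at least 1.19-fold higher, above background in 0 of 4 young animals. In the respiration list 3 of 40 fell, Cox6a2 by 4.48-fold and Ppargc1a by 1.79-fold (median -0.10, camera adjusted p = 1.5e-04, adjusted p = 0.46 with an estimated correlation). Prostate markers had 3 of 8 lower (median -0.72, camera adjusted p = 0.013, adjusted p = 0.46 with an estimated correlation). Andpro was at least 18.4-fold lower (12.1-fold without young replicate 2), and the secretoglobin genes Scgb1d2, outside the list, and Scgb1d4 were at least 21.4 and 17.9-fold lower. Scgb1d2 did not pass in 6 and Scgb1d4 in 7 of the 12 fits that left out 1 animal. The senescence list, which did not pass, had Mmp3 2.57-fold higher and Cdkn2c, the cell cycle inhibitor gene Cdkn1a and Lmnb1 lower by 1.43, 1.27 and 1.42-fold. Fibroblast markers had 3 of 21 higher, including Ano1 and Thy1, and 4 lower, including Pi16 and Gsn (median -0.29, camera adjusted p = 0.048, adjusted p = 0.46 with an estimated correlation). Endothelial markers Cdh5 and Esam fell by 1.27 and 1.23-fold (median -0.11, camera adjusted p = 0.036, adjusted p = 0.46 with an estimated correlation), while 0 erythrocyte and platelet markers passed (median -0.52, camera adjusted p = 0.036, adjusted p = 0.46 with an estimated correlation; limma, 0 higher and 2 lower at an unadjusted p under 0.05). The fibroblast list lost its call without young replicate 2 (-0.25), 3 (-0.31), old freely fed replicate 2 (-0.29) and old restricted replicate 1 (-0.26). The endothelial list lost its call without young replicate 4 (-0.10), old restricted replicate 2 (-0.09) and 4 (-0.13) and moved without young replicate 3 (-0.18) and old restricted replicate 3 (-0.16). It also moved with quantile scaling alone (-0.07) or after normexp (-0.07). The erythrocyte and platelet list lost its call without young replicate 1 (-0.45), 2 (-0.45) and old restricted replicate 1 (-0.50). With no filter on dim probes the fibroblast, endothelial and erythrocyte and platelet lists did not pass (camera adjusted p = 0.15, 0.12 and 0.084). The respiration list moved with quantile scaling alone (-0.05) or after normexp (-0.05), the nerve list with quantile scaling after normexp (-0.16), and the prostate list with normexp (-0.47) and with quantile scaling after it (-0.45).

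Of the immune lists, T and NK cell markers had 1 of 26 past the threshold, Cd2 at 1.51-fold higher, and 0 when adjusted over the list alone (5 higher and 1 lower at an unadjusted p under 0.05, limma; median 0.26, camera adjusted p = 0.013, adjusted p = 0.62 with an estimated correlation). The interferon list passed with 0 single genes (median 0.37, camera adjusted p = 0.039, adjusted p = 0.82 with an estimated correlation; limma, 0 higher and 0 lower at an unadjusted p under 0.05). The T and NK cell list lost its call without young replicate 1 (0.13) and old restricted replicate 3 (0.17). The interferon list lost its call without young replicate 1 (0.31), 2 (0.37), 4 (0.39) and old restricted replicate 3 (0.10) and with quantile scaling (0.39). In the chemokine list Cxcl2 and Ccl3 fell by 6.26 and 1.67-fold, and the list did not pass (median log2 change -0.07, camera adjusted p = 0.53). The macrophage, mast cell, B cell, MHC class II, complement and acute phase lists did not pass, and their single genes were Cx3cr1, down by 1.61-fold, Derl3 and Pax5. Single genes with large changes were Cpeb1, up 3.35-fold (log2 1.74, SE 0.13, adjusted p = 2.3e-04), Krt6c and Ntsr1, up 5.51 and 3.85-fold, Mab21l4, up at least 3.68-fold with 3 of 4 young animals above background, and Cldn3 and the trefoil factor gene Tff2, at least 1.7 and 3.27-fold higher. Slc5a5 was above background in 4 of 4 restricted and 0 of 4 young animals (limma adjusted p = 0.037), at least 2.52-fold higher by its brightest probe. It did not pass in 7 of the 12 fits that left out 1 animal, and another of its probes gave a log2 change of -0.06. Alkal2 and Foxs1 fell by 5.13 and 4.36-fold, Rpl39l1 by at least 2.81-fold with 1 of 4 restricted animals above background, and Rnase2 was at least 8.31-fold lower. Sirpb3 was lower, with 0 of 4 restricted and 2 of 4 young animals above background (limma adjusted p = 0.0019).

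Altogether 651 genes were higher and 1223 lower in restricted old than in young rats (limma), against 827 and 880 with quantile scaling and 683 and 819 with quantile scaling after normexp. Of these, 73 and 113 changed at least 2-fold. Among the dimmest 5107 genes 195 were higher and 291 lower, and among the brightest 5107 these numbers were 100 and 366. The animals did not overlap for 3668 (18.0%) of all genes tested (chance share 2.86%), and 44 of the 68 genes named by rule passed in each of the 12 fits that left out 1 animal. Counts fell by over 1.5 times without young replicates 1 (393 higher, 657 lower) and 2 (368, 722) and old restricted replicates 1 (382 higher), 2 (313, 556) and 3 (278, 459), and slide and scan differ between these groups as well. Genes that no longer passed with normexp were Slc5a5, Scgb1d2, Scgb1d4, Rnase2, Rpl39l1, Asic1, Cdkn1a, Nfe2l2, Cd2, Gsn, Cdh5 and Esam. Cdkn1a and Sod3 did not pass with quantile scaling, nor did Slc5a5, Kcnma1, Stmn2, Asic1, Klf5, Cdkn1a and Ano1 by another probe, nor Nfe2l2 and Gsn without the brightness trend.

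The series' question on prevention was addressed by setting the change with age against the change with restriction. Of the 332 genes higher with age, 74 were lower and 3 higher with restriction, and 255 did not pass there. Of the 428 genes lower with age, 33 were higher and 5 lower with restriction. That made 107 genes with opposite changes and 8 with the same direction, where independent lists of these sizes would give 13.6 and 14.0, values that leave out the shared old freely fed arrays. Simulated unchanged groups held 0.02 calls for age on average, so their overlap of 0 sets no reference for these counts. With the old freely fed animals split into 2 and 2, so that no array was shared, fewer genes passed. The 6 splits gave 4 to 23 opposite changes, against 0.101 to 2.23 for independent lists, and 0 to 5 in the same direction, against 0.086 to 2.63. Only the old freely fed arrays lay in row 2 of a slide, those of the other groups in row 1. An effect of the row would give opposite changes in both comparisons, and these splits do not remove it. Array row, slide and scan therefore cannot be told apart from a prevention of age changes here. Of the genes higher with age, 113 (34.0%) were also higher in restricted old than in young rats, and 184 (43.0%) of those lower with age were also lower there. These 297 genes compare with 36.2 for independent lists, which leaves out the young arrays shared by both comparisons. With the young animals split into 2 and 2, the 6 splits gave 10 to 34 genes, against 0.374 to 3.1 for independent lists. All young arrays lay together in 1 row of 1 slide, and their scaled negative controls were at -9.08, against -10.2 and -9.69 in the old groups. A technical difference of the young arrays would give the same change in both comparisons, and these splits do not remove it. Across all 20426 genes the log2 changes with age and with restriction correlated at r = -0.49, against a mean of -0.45 (95% range -0.76 to -0.03) in 100 simulated unchanged groups, since both comparisons use the old freely fed arrays. The covariance was -0.0500, against -0.0192 simulated, a difference of -0.0308. With the 4 old freely fed animals split into 2 and 2 so that the comparisons shared no array, r was -0.33 to -0.12 over the 6 splits, and the mean covariance was -0.0249. The opposite-direction count was 53, 27, 38 and 70 without young replicates 1 to 4, 54 without old freely fed replicate 2 or 3, and 45, 24 and 37 without old restricted replicates 1, 2 and 4.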

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

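Tests of a single animal, of the share of smooth muscle, of other differences between the slides and of the time of day were chosen only after the results were seen, and those of an intensity-dependent offset and of other splits of the animals were chosen before. In 514 comparisons of the 4 animals of a group, 36 had 1 animal apart from the other 3. They covered named gene levels, list scores, the first 4 principal components, and the arrays' signal, background and correlation with their group. The gap to the nearest of the others, as a share of the whole range of the group, was then over Dixon's critical value for 4 samples. Chance alone sets apart about 1 in 20, or 25.7 here. Old restricted replicate 4 accounted for 10 of the 36, old freely fed replicate 2 for 7 and old restricted replicate 3 for 6. For each count of genes, 1 of 35 splits of the animals, the real one, gave as many. That share of 0.0286 is the smallest that 35 splits can give, so it argues against chance without excluding it. The real counts were 760 with age, 744 with restriction and 1874 between restricted old and young rats, and the highest counts of the other splits were 121, 0 and 0 (limma). In those splits the real difference adds to the spread within groups, which lowers their counts. At an unadjusted p under 0.05 the real counts were 5033, 4210 and 5341, and the highest of the other splits 3098, 1978 and 2326.

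Markers of T and NK cells were higher in old than in young freely fed rats and lower in restricted old rats, and their score, the mean deviation of the list from its mean over all arrays, set old freely fed replicate 2 apart (1.35 against 0.33 to 0.49, gap 0.845 of the range). That animal alone does not account for the change with age, since the median without it was 0.93 of 1.09. A lower share of smooth muscle that raised markers of all other cell types alike is argued against. The list lay 1.14 above the median of 95 markers of urothelium, endothelium, fibroblasts and nerve (bootstrap 95% interval over genes 0.85 to 1.40), which itself was -0.04. That interval does not measure the spread between animals. The smooth muscle list fell with age (median -0.30), so other shifts in cell composition are not excluded. An intensity-dependent offset between slides is argued against by the change with restriction, -0.80 at percentile 0 of 10000 lists matched on brightness, the lowest of which had -0.19. Any other difference between the slides cannot be told apart from restriction, because 0 slides held both old groups. The array row, which set the freely fed old arrays apart from both other groups, cannot be told apart either. A biological difference with age or diet may also account for the pattern and stays untested.

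Clock genes of opposite daily phase changed in opposite directions in restricted rats, and the clock score set old restricted replicate 4 apart (0.44 against 0.23 to 0.26, gap 0.890). An intensity-dependent offset between slides is argued against by the mean size of the change, 0.93 at percentile 100 of 10000 matched lists, the highest of which had 0.54. Within groups, 7 genes of the Per and Dbp phase ran against 4 of the Bmal1 phase over the 12 animals (Pearson's r = -0.80, Spearman's rho = -0.90, exact permutation p within groups 0.00116 and 0.00376 over 13824 orders, 1 relation computed, r = -0.77 without the 2 animals farthest from the median). This is in line with animals differing in clock phase when their tissue was collected, so a different time of day of collection may have contributed to the difference between groups. A shift of the clock by the feeding schedule stays open as well, untested, as do other differences between the slides.

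On old freely fed replicate 2 the first principal component had a gap of 0.855, the interferon score 0.927 (2.45 against -0.25 to -0.05), the complement gene C3 0.831 (2.24 against -0.72 to -0.22), Atp5f1b 0.958, Ces1dl1 0.864 and Wnt6 0.936. Old freely fed replicate 1 stood apart in Acsbg1 (0.845), Dbp (0.843) and Galntl5 (0.855). Old freely fed replicate 3 stood apart in Andpro (0.893, at -5.78 against -10.3 to -9.85) and Sirpb3 (0.833). The senescence score set old freely fed replicate 4 apart (0.892). Among young rats, replicate 1 stood apart in the smooth muscle score (0.895), Chrm3 (0.846), Pax5 (0.914) and Prph (0.839). Young replicate 4 stood apart in the nerve score (0.920, at -7.8e-04 against 0.20 to 0.22) and in P2ry1 (0.891), and young replicate 3 in Bdh1 (0.863). In old restricted replicate 3 the interferon score (0.850, at 1.02 against -0.46 to -0.24), the smooth muscle score (0.856), Ces1dl1 (0.853), Dhcr7 (0.911), Gsn (0.901) and Pax5 (0.873) lay apart. In old restricted replicate 4 these were Adh7 (0.923), Andpro (0.904, at -7.99 against -10.0 to -9.81), Apod (0.900), Atp2a1 (0.903), Ces2c (0.964), Ces2e (0.871), Prdx6 (0.8293), Rnase2 (0.862) and Tsc22d3 (0.891).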

How the results depend on the processing

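Leaving out old freely fed replicates 2 and 4 together was the only alternative chosen after the results were seen. Of 219 calls of named genes, 20 no longer passed with quantile scaling, 5 with median centring, 31 with normexp and 35 without the brightness trend, and none of these changed direction. Of the 54 list calls, 4 were lost with quantile scaling, 3 with normexp, 4 with no filter on dim probes, and all 54 with an estimated correlation in camera (0 held), while 16 held with fry. Another probe of the gene, where there was one, kept the call in 22 of 42 results, lost it in 17 and turned the sign in 3: Cd6 with age (-0.18) and with restriction (0.029), and Slc5a5 between restricted old and young rats (-0.056). The cause was not tested. Signal over background limits what dim probes can show, and with no filter on them 691 genes were higher and 2877 lower with age and 2478 lower in restricted old than in young rats. Scaled negative control spots were themselves 1.09 lower on old freely fed and 0.61 lower on restricted arrays than on young ones. Part of these lower calls may therefore be this offset of probes near background.

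Genes lower with age numbered 152 with quantile scaling, 124 with normexp and quantile scaling and 204 without the brightness trend. With normexp 216 were higher with age and 580 higher with restriction. With array weights the counts were 583 higher and 973 lower with age, 933 and 911 with restriction, and 1019 higher in restricted old than in young rats, with 327 opposite changes. Fits of 2 groups only, which have fewer arrays and leave out the spread of the third group, gave 67 and 27 with age and 213 and 265 with restriction. Both fits have equally many arrays, so their number alone does not account for the larger loss with age. At least 2-fold changes numbered 112 and 17, 26 and 115, and 73 and 113 in the order of the comparisons, with 22 opposite changes. At adjusted p under 0.01 the counts were 21 and 3, 54 and 69, and 120 and 220, with 3 opposite changes. For the remaining moves the cause was not tested.

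The labels number the animals of each group 1 to 4, but no source says that a number marks shared animals or days. Deviations of same-numbered animals correlated at -0.19 to 0.0951 over 12 pairs, 0 of them over 0.1, and 3 of 12 animals correlated best with their own number. The titles carry other animal numbers, which match 5 pairs across groups, at -0.19 to 0.0795, and no block was fitted on them. With the replicate number as a block (replicate block) 215 genes were higher and 283 lower with age and 189 higher with restriction, with 50 opposite changes. With it, 51 named genes and 1 list no longer passed.

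Without each animal in turn, counts ranged over 73 to 378 higher and 48 to 640 lower with age, 117 to 390 and 151 to 458 with restriction, 278 to 758 and 459 to 1331 between restricted old and young rats, 24 to 133 opposite changes and 51 to 57 lists, and the correlation of both effects over -0.57 to -0.41. Between 31 and 87 of the named genes fell short in such a fit, which has fewer animals. Without old freely fed replicates 2 and 4, there were 169 and 25 genes with age, 74 and 165 with restriction and 43 opposite changes, 88 named genes and 7 lists fell short, and the interferon list turned to 0.16 with restriction, as it did without replicate 2 alone, with a range of -0.69 to 0.16 over the fits that left out 1 animal.

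Between scalings, the median turned sign for the receptor and channel, endothelial, fibroblast, detoxification and urothelial lists with age, for the antioxidant, prostate and smooth muscle lists with restriction, and for the heat shock list in restricted old against young rats. Median, mean and test differed in sign for the endothelial and detoxification lists with age, the antioxidant list with restriction and the MHC class II list in restricted old against young rats, none of which passed there. Values of the series table and slide or scan blocks were not run as alternatives, the former being equal to those used, and no slide holding restricted and other animals.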

Other observations

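Tests of gene families and of a lower background were chosen only after the results were seen, and the test of an intensity-dependent offset before. Among 203 families of at least 8 tested members sharing a symbol stem, 9 of 1218 tests passed (Fisher's exact test against 12037 genes with a symbol, each direction and comparison apart). Aldo-keto reductase genes were among those higher with age, 4 of 14 (adjusted p = 0.026): Akr1b8 and Akr1c3, Akr1c13 by 1.43-fold and Akr1c14 by 1.67-fold. Of 10 carboxylesterase genes, Ces2c, Ces2e, Ces2h and Ces5a were higher in restricted old than in young rats (adjusted p = 0.035), Ces2c, Ces2e and Ces5a by 1.64, 1.38 and 1.98-fold. Ces2h was above background in only 1 of 4 young animals, so it was at least 1.58-fold higher, and Ces2e did not pass with normexp. As a family they were not past the threshold among the genes lower with age (adjusted p = 0.14) or in restricted old rats (adjusted p = 0.74). Single members lower in both were Ces1d by 1.96 and 2.45-fold, Ces1dl1 by 2.27 and 2.4-fold and Ces1f by 1.58 and 2.73-fold, Ces1f not passing with age by quantile scaling or normexp. Of these, Akr1b8, Ces2c, Ces5a and, in restricted old rats, the Ces1 genes passed in each of the 12 fits that left out 1 animal.

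Chemokine genes of the Ccl family were lower with restriction in 6 of 15 cases (adjusted p = 1.7e-04). Beside Ccl2 and Ccl3, these were Ccl4 by 2.63-fold, Ccl6 by 2.17-fold, Ccl7 by 2.5-fold and Ccl9 by 1.62-fold, of which only Ccl2 and Ccl3 passed in each fit that left out 1 animal. Restricted rats differed from both other groups, with no call for age, in 367 genes, 162 higher and 205 lower, Ciart and Rnase2 among them. Both comparisons use the 4 restricted arrays, which share a slide. With these split into 2 and 2, fewer genes passed, and the 6 splits gave 36 to 74 such genes, against 0.253 to 3.17 for independent lists. No other group lay on that slide or in that scan, so these splits do not remove an effect of either.

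Of 188 odorant receptor genes 15 were lower with restriction (adjusted p = 0.0019), and of 223 odorant, vomeronasal, trace amine and taste receptor genes together 17 were lower and 5 higher, with a median of -0.08. These probes were dim, and an intensity-dependent offset between slides was left undecided by that median, at percentile 2.72 of 10000 lists of matched brightness. The processed signal of 308 negative control spots was 0.48 higher on the restricted than on the freely fed old arrays on the log2 scale. The means were -9.69 and -10.2 (exact permutation p = 0.0286, the smallest that 4 against 4 animals can give), with the arrays of a group sharing a slide. That signal is already background-subtracted, so it cannot show the level of the background. Before subtraction the median control signal was 44 to 51 on restricted and 47.8 to 49 on freely fed old arrays. A lower background on the slide of the restricted arrays thus stays undecided. Against young rats, whose controls were at -9.08, 0.61 above those of restricted arrays, 28 receptor genes were lower and 7 higher (median -0.17). With age, where controls were 1.09 lower, 1 receptor gene was lower and 1 higher. Slide and restriction cannot be told apart here, and no biological explanation was tested, so the receptor calls may belong to either.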
